A study of Bos taurus and Ovis aries and Capra hircus with 18 samples.

How the data were processed

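The study sampled adult brain and muscle of cattle, sheep and goat, with 3 libraries per tissue and species and 18 in all. Per the labels, RNA was taken from frozen tissue with TRIzol, selected with oligo(dT) beads, sheared and copied with random hexamers. The submitters' processing notes name Trimmomatic 0.39 for trimming, STAR 2.7.6 for alignment and featureCounts, with no version, for counting, and ARS-UCD1.2 as the only genome build. The builds of sheep and goat are not given in the sources used here, and neither are strandedness, the handling of reads with several placements or the counting of pairs. The deposited values are raw read counts, in the unit count per gene and library, with separate counts for each species on its own Ensembl gene models. Brain region, muscle, age, sex and the meaning of the replicate letters are not given in the sources used here.

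Groups were set from the sample titles before the data were examined, along with the comparisons, the gene lists, the thresholds and most alternatives. Library totals ran from 20730803 to 58514630 counts and 17204 to 20221 genes had at least 1 count. At such depth a gene at 1 CPM of the library total has some 20 counts or more per library. For most genes named here the spread between libraries, and not counting, therefore sets the precision. No library was left out.

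Cattle genes were named by position, because 0 identifiers matched those of the RefSeq table, which is on a later build. A name was given where the spans overlapped by at least 0.5 of their union and the second best overlap was at most 0.5 of the best. This named 15849 genes, of which 5054 (31.9%) had an identical start or end. All coordinates printed are those of the count files.

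Sheep and goat genes were matched to cattle by exon structure. This was chosen after the files were seen, in place of the symbols that had been planned, and the plan had been to make no comparison between species without symbols. A match needed at least 2 shared pairs of neighbouring exon lengths, and a second pass accepted at least 1 shared exon length between matched neighbours, with 5 neighbours on each side and a rank distance of at most 15. Of the 13495 genes matched in 3 species, 9867 came from the first pass and 3628 from the second. When matches were held out, the second pass found the same partner in 99.9%, 99.8% and 99.8% of cases for cattle and sheep, cattle and goat, and sheep and goat. Those held out had all passed the first pass, so these rates do not measure the accuracy of matches that only the second pass found. Median exonic lengths were 2551 in cattle, 1717 in sheep and 2061 in goat, so the exonic length of each species entered the fits as an offset.

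Counts were fitted with edgeR 4.0.16 (quasi-likelihood, robust) after filterByExpr and trimmed-mean (TMM) scaling in R 4.3.3. Brain was compared with muscle within each species and over all species with species as a term. The interaction of species with tissue was tested over all species and for each pair, and species were compared within each tissue for each pair and for each species against the mean of the others. A gene was called at a Benjamini-Hochberg (BH) adjusted p below 0.05 and an absolute log2 fold of at least 1. Similarity between libraries was the Spearman correlation of log2 CPM of the matched genes.

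The 39 lists of marker and pathway genes held 513 symbols, of which 464 were named in cattle and 359 matched in the 3 species. They were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, then with an estimated correlation and with fry, with BH adjustment over the lists of a comparison. Calls of list members were made over all genes and also adjusted over the list alone. The markers of sex chromosomes (7 listed, 0 named) could not be read, none of the 13 mitochondrially encoded genes was matched, and the red blood cell list, with 3 matched genes, was not tested over the 3 species.

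Genes were chosen for naming by a rule set beforehand, and only those with a symbol. Per direction these were the 12 genes called in all 3 species with the same sign, a mean log2 CPM of at least 5 in the higher tissue and the largest mean fold. Per list and comparison they were the up to 4 members of lowest adjusted p, up to 2 called against the list median and members not called where the text says so. For the interaction they were 5 genes per pair and direction, and within a tissue 4 per species and direction whose 3 libraries all lay beyond the 6 others, both at a mean log2 CPM of at least 3. Not every gene that met the rule is described here. Exceptions are COX1, CYTB and the other mitochondrially encoded genes, named after their values were seen, and genes named only because a setting ended their call. A fold against a group with 0 counts is a floor at 3 counts over the group, and for groups of 1 to 3 counts levels are given in place of folds.

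Alternatives were relative log (RLE) and other scaling, DESeq2 1.42.0, limma-voom, other count filters, other fold thresholds, the replicate letter as a block, no length correction, genes with exonic lengths within 1.2 times, and each library left out. Added after the data were seen were a fit without sheep brain C and goat muscle C, a stricter match with at least 5 shared pairs and the first pass alone. Group labels were also split in other ways, 10 within a species and 100 otherwise, to see what counts arise without the real grouping. The fits were tested on simulated data with added changes. In sheep a change of log2 1 was called in 1.25% of the changed genes and of log2 2 in 13.8%, and a change of log2 4, added after the first 2 sizes were seen to be missed, in 95.0%. Cattle gave 38.8%, 92.5% and 92.5% and goat 13.8%, 77.5% and 100%. For the interaction of cattle and sheep these were 1.25%, 38.8% and 100%. False calls numbered 3 to 14 per fit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and data.table (version 1.17.8) in R, served for matching, tables and plots.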

Results

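Adult brain and muscle of cattle, sheep and goat were compared by sequencing of poly(A)-selected RNA, with 3 libraries in each of 6 groups of tissue and species. The labels name neither the brain region nor the muscle sampled. The cattle brain libraries held 42891698 to 58514630 counts and the cattle muscle libraries 40878387 to 53560617. Sheep brain held 25162316 to 30432512, sheep muscle 43007347 to 46302643, goat brain 20730803 to 29496749 and goat muscle 23250777 to 25037038. Each species had been counted on its own Ensembl gene models, with 27607 genes in cattle, 26478 in sheep and 27271 in goat. The labels do not say that the replicate letters A, B and C stand for separate animals, so every p-value below measures only the spread between these samples. Standard errors are given after ± beside log2 values and standard deviations (SD) beside levels.

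Sheep and goat genes carried identifiers only, and comparing species needed a partner for each. Genes were paired with cattle by the lengths of their neighbouring exons, a step chosen after the files were seen in place of the matching by symbol that had been planned, and the plan had been to make no comparison between species without symbols. The pairing gave 11024 partners between cattle and sheep, 11048 between cattle and goat and 11177 between sheep and goat. Gene order was kept in 99.4%, 98.0% and 97.7% of them. Shuffled exon lengths gave 538, 520 and 590 pairs, of which 0 kept gene order. In the 3 species together 13495 genes were matched, and 11800 of them carried a symbol from cattle. Levels of nuclear genes are CPM, here counts scaled to the library total after its trimmed-mean (TMM) adjustment. Those compared between species are also corrected for the exonic length of the gene model in each species. Levels of mitochondrially encoded genes are CPM on the library total alone.

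Tissue set the resemblance between libraries far more than species did. Brain of cattle resembled brain of sheep or goat, and muscle resembled muscle, with a mean Spearman correlation of 0.887 (SD 0.0564) between libraries of the same tissue from different species. Libraries of different tissues from the same species reached only 0.574 (SD 0.0243), and libraries within a group 0.960 (SD 0.0556). The first principal component parted brain from muscle and held 71.3% of the variance, and the second held 9.46%. Sheep brain C stood apart from its own group, with a mean correlation of 0.813 with sheep brain A and B, which reached 0.990 with each other. Goat muscle C followed with 0.944. Both were kept except where a fit without them is named.

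**Figure D1:**
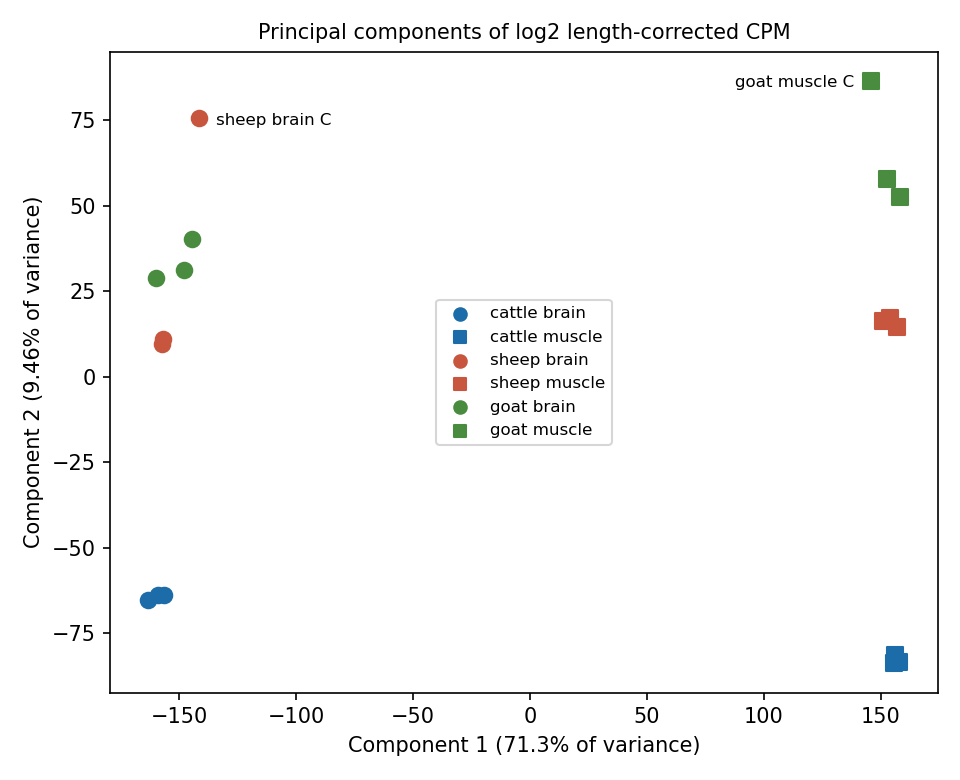
Principal components of log2 length-corrected CPM of the matched genes, each point a library, coloured by species and shaped by tissue. Sheep brain C and goat muscle C lie away from their groups.

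Which genes mark brain against muscle was asked within each species first. Single genes are named first, and lists of genes follow with the fit of all species. CHGB, a granin of dense-core secretory granules, reached 431 CPM in cattle brain (SD 44.6) against 0.129 in muscle, a log2 difference of 11.65 ± 0.34 (edgeR, Benjamini-Hochberg (BH) adjusted p = 5.17e-08), and in sheep 428 CPM (SD 155) against 0 in every muscle library, at least 13660-fold. In goat CHGB stood at 439 CPM (SD 121) in brain and 0.0553 in muscle. SNAP25, which drives fusion of synaptic vesicles, was higher in brain by 11.25 ± 0.32 in cattle and 11.47 ± 0.56 in goat (edgeR, BH adjusted p = 5.08e-08 and 7.89e-07). In sheep SNAP25 averaged 1047 CPM in brain and 0.0101 in muscle. The genomic spans in cattle are chromosome 13, 48069187 to 48084157 on the plus strand, for CHGB and chromosome 13, 3478001 to 3561819 on the plus strand, for SNAP25. Floors of this kind, here 3 counts over the silent group, cover counting error only, whereas the standard errors also hold the spread between libraries.

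Other genes followed these on the brain side. SLC12A5, the chloride extruder of mature neurons, was higher in cattle brain by 11.47 ± 0.41 and in goat brain by 11.74 ± 0.43 (edgeR, BH adjusted p = 9.56e-08 and 4.68e-07), and in sheep at least 8973-fold. SNCB, the presynaptic beta-synuclein, was higher by 10.93 ± 0.36 in cattle and 11.53 ± 0.64 in goat (edgeR, BH adjusted p = 7.52e-08 and 1.19e-06) and at least 17860-fold in sheep. The bicarbonate transporter SLC4A10 was higher by 10.66 ± 0.40 in cattle (edgeR, BH adjusted p = 1.28e-07), at least 1819-fold in sheep and at least 1801-fold in goat. FBXL16, an F-box protein, was higher by 11.55 ± 0.41 in cattle (edgeR, BH adjusted p = 1.01e-07) and averaged 549 CPM in sheep brain and 399 in goat brain. The GABA receptor subunit GABRD was higher in sheep brain at least 2807-fold and in goat brain at least 700.3-fold. KCNV1, a modulatory potassium channel subunit, was higher at least 1502-fold in sheep and 924.6-fold in goat. MPPED1, a metallophosphoesterase, averaged 71.2, 88.1 and 310.0 CPM in brain of cattle, sheep and goat, and the glutamate receptor GRM3 55.9, 153 and 204, with at most 1 count in any muscle library.

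On the muscle side PPP1R3A and UCP3 came first in the ranking over the 3 species by fitted fold, followed by MYOT, CKM and MYH1. The first places are not firm, since they rest on folds fitted against groups at 0 counts. PPP1R3A was fitted at -18.87 in sheep against -16.01 at the floor, and UCP3 at -16.29 in goat against -13.66. CKM, the creatine kinase that buffers ATP, reached 19340 CPM in cattle muscle (SD 1271), 47720 in sheep (SD 2699) and 40700 in goat (SD 539) against 2.31, 1.07 and 1.98 in brain. Its log2 differences were -13.04 ± 1.37, -15.44 ± 1.89 and -14.36 ± 1.69 (edgeR, BH adjusted p = 4.13e-05, 0.000810 and 9.0e-05). MYH1, a fast myosin heavy chain, was lower in brain by -12.61 ± 1.36, -15.79 ± 2.01 and -13.38 ± 1.09, and the fast troponin TNNI2 by -13.42 ± 0.80, -13.62 ± 0.64 and -13.20 ± 0.74, in the same order of species. Troponins TNNT3, TNNC2 and TNNC1 and the myosin light chain MYL11 followed, with TNNT3 at -12.74 ± 1.17, -12.93 ± 1.47 and -14.25 ± 1.38, TNNC2 at -13.21 ± 1.23, -13.73 ± 1.46 and -13.68 ± 1.38, TNNC1 at -13.40 ± 1.28, -12.56 ± 1.45 and -13.74 ± 1.35 and MYL11 at -13.01 ± 1.197, -14.31 ± 1.03 and -14.21 ± 1.47. PPP1R3A, which targets a phosphatase to glycogen, was lower in sheep brain at least 66020-fold, the uncoupling protein UCP3 in goat brain at least 12980-fold and the calcium channel subunit CACNG1 in cattle brain at least 6278-fold. The Z-disc proteins MYOT and MYPN were lower in cattle brain by -13.18 ± 1.31 and -12.54 ± 0.69. CKM lies in cattle on chromosome 18, 52956472 to 52966223 on the minus strand, and MYH1 on chromosome 19, 29483027 to 29507056 on the minus strand.

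Brain carried more genes above muscle than below it in each species. Of 16428 genes tested in cattle, 5575 were higher in brain and 4162 in muscle. Sheep had 4456 and 2999 of 15616, and goat 4972 and 3669 of 15825, at an edgeR BH adjusted p below 0.05 and a 2-fold difference. How the calls divide depends on the scaling: the brain share of the calls was 57.3%, 59.8% and 57.5% with trimmed-mean scaling and 75.9%, 83.4% and 77.8% with totals alone, where the median log2 difference over all genes moved from 0.09, 0.17 and 0.12 to 0.76, 1.12 and 0.86.

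Many of the same genes marked the tissues in the 3 species, with 3602 genes called in all 3 at either sign, 2111 in 2 and 2339 in 1 only. CHGB and SNAP25 belong to 2219 matched genes called higher in brain in every species, where independent lists of the same sizes would share 290.5, and CKM and MYH1 belong to 1347 called higher in muscle, where 119.7 would be shared. Of 11161 matched genes tested in the 3 species, 134 were called with opposite signs in at least 2 of them. The log2 differences correlated with Pearson coefficients of 0.880 between cattle and sheep, 0.898 between cattle and goat and 0.914 between sheep and goat, and had the same sign in 80.02%, 82.8% and 81.6% of genes. In the fit of all 18 libraries with species as a term, 3787 of 12233 genes were higher in brain and 2868 in muscle.

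Neuronal genes led the brain side of that common fit. RBFOX3, the splicing factor that marks mature neurons, was higher in brain by 8.61 ± 0.24 and ENO2, the neuronal enolase, by 10.48 ± 0.33 (edgeR, BH adjusted p = 3.19e-15 and 7.22e-15). At synapses the vesicle protein SYP was higher by 9.53 ± 0.34 and the SNARE protein STX1A by 9.87 ± 0.45 (edgeR, BH adjusted p = 3.25e-14 and 6.2e-13), and of the receptors for glutamate the subunit GRIA2 by 10.69 ± 0.52 and its scaffold DLG4 by 6.65 ± 0.23 (1.45e-12 and 2.03e-14). SLC32A1, which loads GABA into vesicles, averaged 94.4, 87.6 and 68.1 CPM in cattle, sheep and goat brain, and GAD1, which makes GABA, 188, 137 and 195. The sodium channel SCN2A was higher by 10.34 ± 0.56 and the calcium channels CACNA1A and CACNA1B by 4.95 ± 0.25 and 6.61 ± 0.40 (edgeR, BH adjusted p = 5.63e-12, 2.82e-12 and 3.23e-11). The exceptions were HOMER1, a scaffold of glutamate receptors, at -0.65 ± 0.31, and the calcium buffer CALB1, neither called. All 15 neuronal genes, all 13 genes of vesicle release and all 11 ion channels were called higher, as were 10 of 11 in each of the lists of excitatory and inhibitory neurons. The list medians were 10.48, 9.53, 6.61, 9.51 and 11.10, the last 2 at 9.27 and 10.19 with genes near 0 at the floor (limma camera, BH adjusted p = 5.89e-09, 2.04e-07, 2.37e-05, 2.42e-05 and 5.33e-05). Only the list of excitatory neurons lost its call with an estimated correlation (camera, BH adjusted p = 0.0572 with an estimated correlation). Here and below, counts of list members made over all genes and those adjusted over the list alone were equal unless both are given.

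Single genes of astrocytes and myelin stood on the brain side, and single genes of connective tissue on the muscle side. Among astrocyte genes GFAP, the intermediate filament, was higher in brain by 11.60 ± 0.56, ALDOC by 10.61 ± 0.43 and the glutamate transporters SLC1A3 and SLC1A2 by 6.76 ± 0.44 and 9.67 ± 0.72 (edgeR, BH adjusted p = 1.12e-12, 1.2e-13, 7.41e-11 and 5.73e-10). MAG, an adhesion protein of myelin, was higher by 7.97 ± 0.40 (edgeR, BH adjusted p = 1.96e-12), and OPALIN and ERMN averaged 26.2, 133 and 172 CPM and 27.5, 55.4 and 109 CPM in brain of cattle, sheep and goat. In muscle, DCN, a collagen-binding proteoglycan, was higher with a log2 of -4.84 ± 0.31 and COL6A1 with -5.38 ± 0.35 (edgeR, BH adjusted p = 5.56e-11 and 9.1e-11). PECAM1, an endothelial adhesion protein, stood at -2.58 ± 0.30, whereas SLC2A1, the glucose carrier of brain vessels, went the other way at 5.04 ± 0.31 (edgeR, BH adjusted p = 2.81e-07 and 4.59e-11). SMTN of smooth muscle stood at -3.17 ± 0.31 and PLIN4, which coats lipid droplets, at -8.82 ± 0.46, while FASN, the fatty acid synthase, was higher in brain by 2.33 ± 0.24 (edgeR, BH adjusted p = 3.13e-08, 3.21e-12 and 7.38e-08).

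As lists, 12 of 13 oligodendrocyte genes (median 6.07) and 9 of 11 astrocyte genes (4.79) were higher in brain, and 8 of 10 fibroblast genes (-3.12) were higher in muscle (camera, BH adjusted p = 1.24e-05, 0.000491 and 0.000906), but 0.135, 0.0655 and 0.124 with an estimated correlation. Smooth muscle had a median of -1.02 with 4 of 7 genes higher in muscle, 5 when adjusted over the list alone (camera, BH adjusted p = 0.0225, and 0.0787 with an estimated correlation). The fibroblast and smooth muscle calls also ended with the stricter match. BCAN, a proteoglycan of the brain matrix, was higher in brain by 11.08 ± 0.47 and SOX6 higher in muscle at -2.54 ± 0.51, and the list of oligodendrocyte precursors, 5 genes with 2 higher and 1 lower in brain, was not called (median -0.13, camera, BH adjusted p = 0.853). CSF1R, the receptor that sustains microglia, was higher in brain by 3.26 ± 0.26 and the scavenger receptor CD163 higher in muscle at -2.30 ± 0.31, and the microglial list (7 genes, 4 higher and 1 lower, median 1.14) was not called (camera, BH adjusted p = 0.279). Endothelium (10 genes, 1 higher and 6 lower, median -1.17) and adipocytes (8 genes, 2 higher and 4 lower, median -2.67) were not called either (camera, BH adjusted p = 0.0861 and 0.134).

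**Figure D2:**
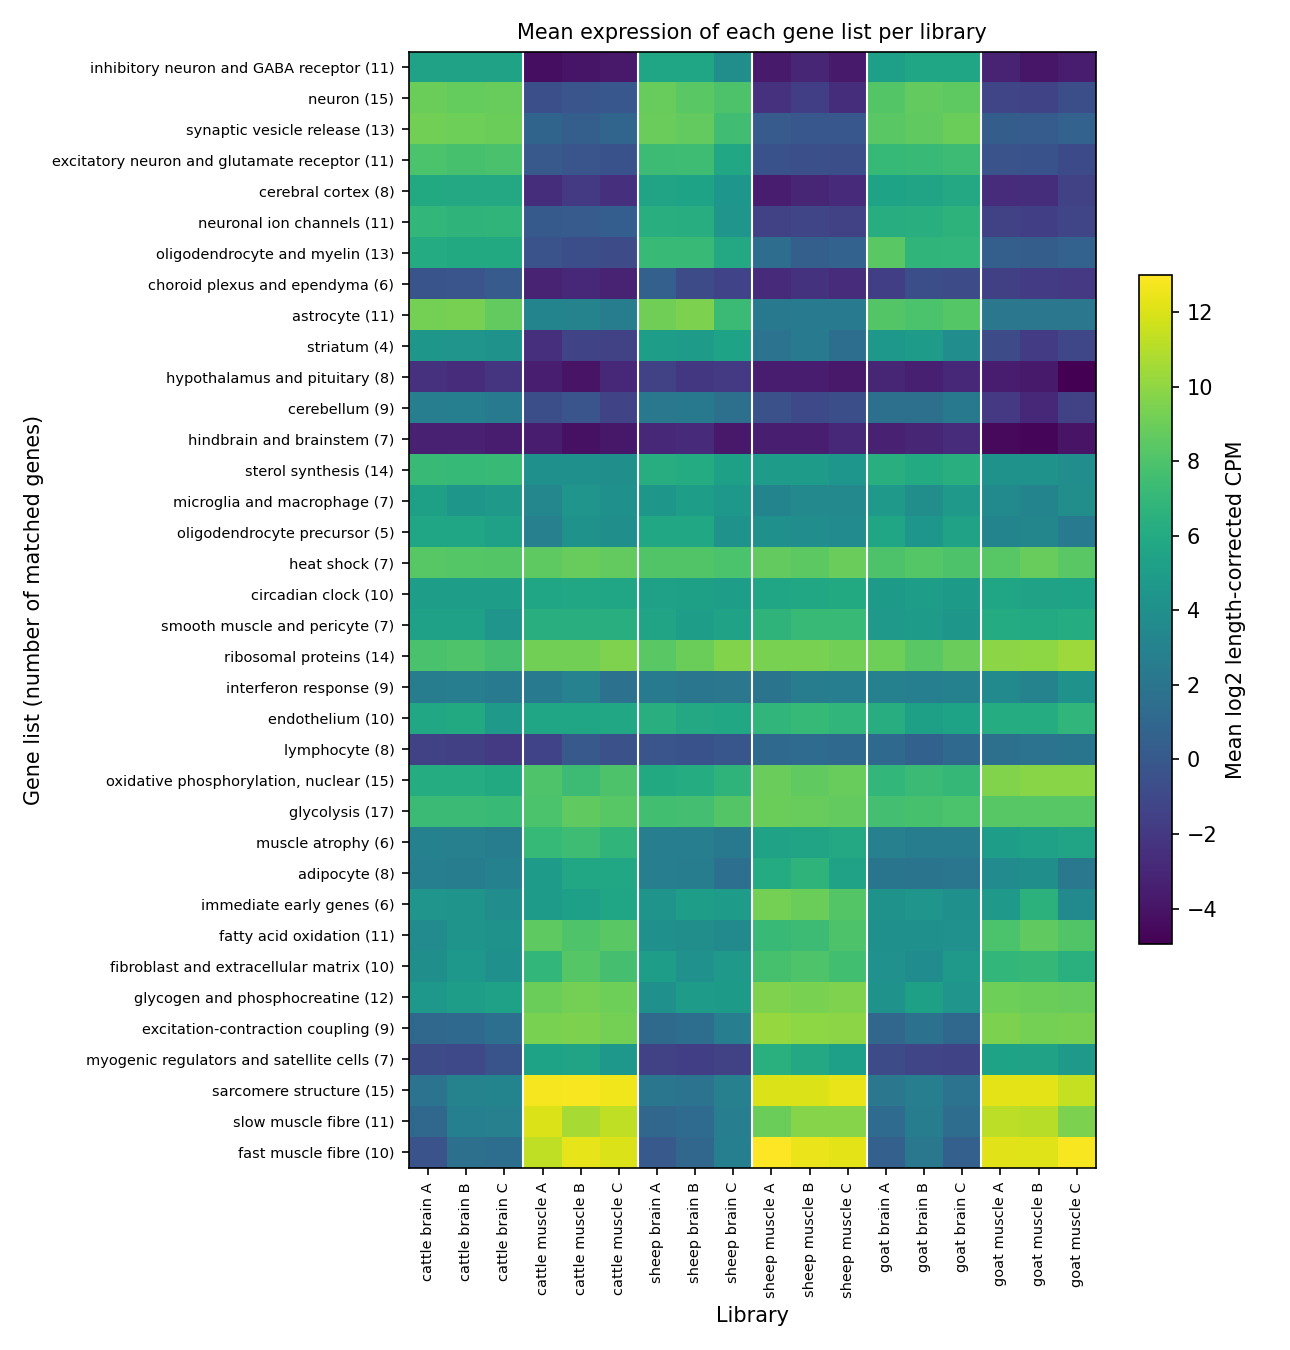
Mean log2 length-corrected CPM of each gene list in each library, with the number of matched genes in brackets. White lines part the 6 groups.

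The contractile apparatus filled the muscle side. NEB, the ruler of the thin filament, was lower in brain by -10.21 ± 0.33 and DES, the filament that links sarcomeres, by -9.26 ± 0.37 (edgeR, BH adjusted p = 8.4e-15 and 1.2e-13). ATP2A1, the calcium pump of fast fibres, stood at -11.71 ± 0.37 and MYH7, the slow myosin, at -10.51 ± 0.55 (edgeR, BH adjusted p = 7.88e-15 and 4.02e-12), and STAC3 and CACNA1S, which couple excitation to calcium release, at -10.20 ± 0.47 and -6.87 ± 0.31 (6.44e-13 and 6.09e-13). The regulators MYOG and MYOD1 stood at -9.51 ± 0.47 and -7.96 ± 0.50 (edgeR, BH adjusted p = 1.76e-12 and 5.19e-11), and TRIM63, which tags muscle proteins for breakdown, at -10.50 ± 0.43 (1.51e-13). PVALB, a calcium buffer of fast fibres and of interneurons, was the exception, higher in brain by 4.53 ± 0.62 (edgeR, BH adjusted p = 2.61e-06), and MEF2C was not called. All 15 sarcomere genes, all 11 slow-fibre genes, all 9 genes of coupling, 9 of 10 fast-fibre genes, 6 of 7 myogenic regulators and 5 of 6 atrophy genes were higher in muscle. Their medians were -9.26, -10.51, -7.19, -12.51, -7.96 and -2.35 (camera, BH adjusted p = 1.02e-11, 1.51e-06, 4.09e-07, 1.47e-06, 0.000358 and 0.0157). With an estimated correlation the sarcomere and coupling lists kept their calls (camera, BH adjusted p = 0.00988 for both), and the slow, fast, myogenic and atrophy lists gave 0.0897, 0.0785, 0.0675 and 0.0897. The atrophy list also lost its call among first-pass matches.

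ENO3, the muscle enolase, was lower in brain by -11.63 ± 0.43 where ENO2 was higher, and PFKP, the platelet form of phosphofructokinase, was higher by 3.29 ± 0.18 (edgeR, BH adjusted p = 3.79e-14 and 5.76e-12). Glycogen phosphorylase split the same way, with PYGM at -6.08 ± 0.23 and PYGB at 5.62 ± 0.21, and so did creatine kinase, with CKB at 7.16 ± 0.37 against CKM at -14.32 ± 1.15 (edgeR, BH adjusted p = 4.56e-14, 3.79e-14, 2.58e-12 and 1.82e-09). ETFDH and SLC25A20 of fat oxidation stood at -3.05 ± 0.15 and -2.32 ± 0.15, and COX7A1 and UQCRC2 of the respiratory chain at -3.94 ± 0.28 and -2.39 ± 0.17 (edgeR, BH adjusted p = 8.46e-13, 7.17e-11, 3.12e-10 and 3.36e-10). SQLE and MSMO1 of cholesterol synthesis were higher in brain by 4.45 ± 0.32 and 2.83 ± 0.21 (edgeR, BH adjusted p = 3.91e-10 and 7.82e-10). Glycolysis as a list was mixed, 7 genes higher and 10 lower of 17 (median -1.98, camera, BH adjusted p = 0.204). The other lists were called: glycogen and phosphocreatine (2 higher and 9 lower of 12, median -4.63), fat oxidation (11 of 11 lower, -2.74), the nuclear genes of the respiratory chain (14 of 15 lower, -1.93), ribosomal proteins (8 of 14 lower, -1.09) and sterol synthesis (11 of 14 higher, 2.18), with camera, BH adjusted p = 0.000783, 1.54e-05, 4.09e-07, 0.00240 and 0.00150. With an estimated correlation the last 3 lost their calls (camera, BH adjusted p = 0.0897, 0.427 and 0.306). The glycogen call ended with the stricter match and the ribosomal call among genes of similar exonic length.

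Whether brain and muscle differ alike in the 3 species was asked by the interaction of species with tissue. EGR3, an early-response transcription factor, averaged 99.2 CPM in cattle brain and 0.922 in cattle muscle but 35.6 and 95.0 in sheep, so that the tissue difference of cattle exceeded that of sheep by 8.15 ± 0.93 (edgeR, BH adjusted p = 4.45e-05). It lies in cattle on chromosome 8, 69996238 to 70000191 on the minus strand. KY, a protein of the muscle cytoskeleton, averaged 4.53 CPM in cattle muscle and 152 in sheep muscle and MXRA5, a matrix protein, 7.34 and 34.7, with 27.1 in cattle brain and 1.98 in sheep brain (interactions of 7.47 ± 1.08 and 6.01 ± 0.87, edgeR, BH adjusted p = 0.000287 and 0.000301). In the other direction MYH6, a cardiac myosin, stood at 70.7 CPM in cattle muscle (SD 47.95) and 3.78 in sheep muscle but at 0.883 in cattle brain and 23.1 in sheep brain (SD 11.4), above sheep muscle. ACTC1, the cardiac actin, stood at 868 (SD 870) and 46.0 in muscle of these and at 0.389 and 3.12 in brain (interactions of -8.93 ± 1.06 and -7.23 ± 1.34, edgeR, BH adjusted p = 6.17e-05 and 0.00174). ACTC1 lost its calls with limma-voom. CLCN1, the chloride channel of muscle, was alike in muscle of all 3 species (131, 134 and 143 CPM) but reached 27.7 CPM in sheep brain against 0.230 in cattle brain (-6.85 ± 0.57, edgeR, BH adjusted p = 1.66e-06). MLC1, an astrocyte membrane protein, averaged 2.67 CPM in cattle muscle and 0 in sheep muscle. PPP1R3A and SNCB were called as well, on sheep groups at 0, and lost their calls under several settings, among them limma-voom.

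Cattle and goat differed in the interaction through genes of either tissue. ACSBG1, which activates long fatty acids, averaged 76.5 CPM in goat muscle (SD 36.5) against 0.104 in cattle and 0.0603 in sheep, and stood at 151, 257 and 95.2 CPM in brain of cattle, sheep and goat (cattle against goat 10.25 ± 0.84, edgeR, BH adjusted p = 3.23e-06). PCBD1, which recycles the cofactor of aromatic hydroxylases, averaged 31.3 CPM in goat muscle against 1.17 and 2.95 (cattle against goat 6.21 ± 0.52, sheep against goat 6.09 ± 0.51, edgeR, BH adjusted p = 3.39e-06 and 6.35e-06). LGI1, a secreted synaptic protein, VWA5A and the decarboxylase DDC gave 7.30 ± 0.75, 7.27 ± 0.75 and 6.92 ± 0.69 between cattle and goat (edgeR, BH adjusted p = 1.48e-05, 1.48e-05 and 1.27e-05), DDC more through brain, with 25.1 CPM in cattle and 0.785 in goat. Cattle muscle stood out instead for SLC7A8, an amino acid carrier, with 1015 CPM (SD 429) against 32.2 and 5.43, for GREB1, a target of estrogen, with 220 CPM against 14.3 and 2.01, and for MSRA, which repairs oxidised methionine, with 164 CPM (SD 10.03) against 5.21 and 6.14. Their interactions between cattle and goat were -6.24 ± 0.63, -6.07 ± 0.79 and -5.64 ± 0.31, and COL6A3 gave -5.53 ± 1.05 (edgeR, BH adjusted p = 1.27e-05, 0.000182, 1.84e-08 and 0.00281), the last through brain, with 1.42 CPM in cattle and 58.3 (SD 60.2) in goat. SLC30A3, the zinc carrier of vesicles, averaged 4.85 CPM in cattle muscle and 0.0518 in goat muscle.

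Between sheep and goat, RUNDC3A, a neuronal effector protein, gave 7.67 ± 0.79, ACTC1 6.401 ± 1.32 and CILP2, a cartilage protein, 5.40 ± 0.96 (edgeR, BH adjusted p = 3.75e-05, 0.0105 and 0.00449). NR4A2, an early-response nuclear receptor with 271 CPM in sheep muscle and 6.93 in goat muscle, gave -4.88 ± 0.62, CHRNE of the muscle acetylcholine receptor, with 413 and 30.3, -5.41 ± 0.80, PLIN1, a lipid droplet protein with 47.6 and 0.957, -4.85 ± 0.81, and the vesicle protein RAB26, with 31.4 and 1.08, -4.62 ± 0.69 (edgeR, BH adjusted p = 0.000254, 0.00127, 0.00313 and 0.00127). MIGA1, a mitochondrial fusion protein, averaged 837 CPM in sheep muscle (SD 133) against 8.86 in cattle and 18.9 in goat, with 7.72 ± 0.77 for cattle against sheep and -7.20 ± 0.76 for sheep against goat (edgeR, BH adjusted p = 1.14e-05 and 5.07e-05). Its sheep model, on chromosome 1 from 58352681 to 58491712 on the plus strand, has 32 exons against 16 in cattle and 19 in goat. It is therefore doubtful that the sheep values measure the same gene.

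In all, 3029 of 12233 genes differed between species in their tissue difference. The pairs gave 2396 genes for cattle against sheep (1051 with a more positive difference in cattle), 1607 for cattle against goat (830) and 868 for sheep against goat (530), by edgeR at a BH adjusted p below 0.05 and a 2-fold difference. The count for cattle against goat was 1067 without cattle brain A, 2682 without sheep brain C and 2756 without sheep brain C and goat muscle C. That for sheep against goat was 437 without goat brain A, 491 without goat brain C, 448, 420 and 437 without sheep muscle A, B or C, 545 without goat muscle C and 1668 with DESeq2. Shares with a positive sign also hung on scaling, 51.7% for cattle against goat and 61.1% for sheep against goat with trimmed-mean scaling and 65.3% and 72.3% with totals alone, and the median log2 for sheep against goat moved from -0.01 to 0.11 and for cattle against goat from -0.07 to 0.05 with relative log scaling.

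Lists of sterol, ribosomal, early-response and atrophy genes were called in the interaction, and none kept its call with an estimated correlation. FDFT1, which commits farnesyl units to sterols, exceeded in cattle by 2.64 ± 0.42 against sheep and by 2.64 ± 0.42 against goat (edgeR, BH adjusted p = 0.000627 and 0.000855). SQLE averaged 319 CPM in cattle brain (SD 4.55), 107 in sheep brain (SD 25.6) and 84.8 in goat brain. The sterol list was higher in cattle against sheep (median 1.996, 11 of 14 genes) and against goat (0.88, 4 genes, 5 over the list alone) and lower in sheep against goat (-1.04, 2 genes, 5 over the list alone), with camera, BH adjusted p = 4.12e-06, 0.0213 and 0.0381, and 0.395, 0.904 and 0.724 with an estimated correlation. HMGCS1, LSS and MVD, which passed between cattle and goat, and SQLE between sheep and goat lost their calls in several settings, limma-voom among them. RPL5, a ribosomal protein, gave -1.79 ± 0.29 for cattle against sheep and 1.25 ± 0.29 for sheep against goat (edgeR, BH adjusted p = 0.000776 and 0.0191). Its second call was lost without sheep muscle C. The ribosomal list had medians of -1.11 (5 of 14 genes lower, 11 over the list alone) and 1.18 (1 higher, 8 over the list alone), with camera, BH adjusted p = 0.000192 and 8.26e-05, and 0.973 and 0.772 with an estimated correlation. Much of both came from sheep brain C, without which they were -0.71 and 0.68. The sterol median for sheep against goat was -0.76 without that library. Both ribosomal calls and the sterol call between cattle and goat were lost with fry, and the sterol call between sheep and goat with fry, without sheep brain B, sheep muscle A or goat muscle A and without both sheep brain C and goat muscle C. EGR3 gave -4.57 ± 0.86 for sheep against goat (edgeR, BH adjusted p = 0.00643), and the list of early-response genes -2.78 (1 of 6 lower, 5 over the list alone, camera, BH adjusted p = 0.00140, and 0.724 with an estimated correlation). Without goat muscle B that list gave -4.18.

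FOXO1, the transcription factor of atrophy, averaged 416 CPM in cattle muscle (SD 62.8) against 36.9 in sheep (SD 9.31) and 27.0 in goat (SD 3.78), and GADD45A, a stress response gene, 738 (SD 86.1) against 31.5 and 33.9. Between cattle and goat FOXO1 gave -3.51 ± 0.70, GADD45A -3.05 ± 0.48, the ubiquitin ligase FBXO32 -3.73 ± 0.81 and BNIP3 of mitophagy -2.02 ± 0.38 (edgeR, BH adjusted p = 0.00398, 0.000847, 0.00625 and 0.00264). The atrophy list had a median of -2.54 (4 of 6 lower, with 1 higher over the list alone), with camera, BH adjusted p = 0.0270, and 0.249 with an estimated correlation. The call was not kept among genes matched in the first pass of the exon comparison.

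Species were then compared within brain, where species, genome, gene models and animals cannot be told apart. Cattle brain exceeded both others in TIMM44, a motor of mitochondrial import, with 1166 CPM (SD 340) against 74.4 and 38.9 (4.44 ± 0.33), in CD38, which consumes NAD, with 132 against 1.30 and 30.04 (4.39 ± 0.39), in AOX1, an aldehyde oxidase, with 154 against 18.5 and 12.01 (3.37 ± 0.35) and in FOLH1, which splits N-acetylaspartylglutamate, with 142 against 2.95 and 76.4 (3.23 ± 0.49), by edgeR with BH adjusted p = 0.000131, 0.000179, 0.000393 and 0.00238. It fell below them in SPON2, a matrix protein, by -4.93 ± 0.45 (edgeR, BH adjusted p = 0.000212). TPI1 of glycolysis and the ribosomal RPL19 stood at -6.86 ± 0.49 and -5.59 ± 0.45 (edgeR, BH adjusted p = 0.000131 and 0.000160), both uncertain because near-identical copies may share their reads. C17H22orf15 averaged 459 CPM in goat brain, 21.4 in sheep brain and 0.0470 in cattle brain, but its goat model has 2 exons over 5370 bases against 4 over 693 in cattle and 5 over 486 in sheep, so it is doubtful that the same gene was measured. Sheep brain exceeded the others in EIF5B, a translation factor whose sheep model has 7 exons against 27 in cattle and goat (5.79 ± 0.31), in SPON2 (4.24 ± 0.34), in CILP2 (4.01 ± 0.68) and in TNFRSF25, a death receptor (3.93 ± 0.85), and fell below them in the urea carrier SLC14A1 (-5.66 ± 1.36), CD38 (-5.59 ± 0.53) and NME7 (-5.34 ± 0.44), by edgeR with BH adjusted p = 2.43e-05, 0.000193, 0.00523, 0.0135, 0.0213, 0.000452 and 0.000193. In sheep brain CILP2 averaged 160 CPM (SD 205) and TNFRSF25 116 (SD 160), so that 1 library carried each mean. The sheep model of EIF5B has 458 bases against 3677 in cattle and 3682 in goat, so the length correction makes much of its value. Sheep models of CD38 and FOLH1 are the longest of the 3 species, at 5981 and 5280 bases. Those of cattle have 2877 and 3824 and those of goat 4713 and 2514. Whether these models make the low sheep values was not tested. The call of SLC14A1 was lost without sheep brain B. Goat brain exceeded them in DNAI1 of ciliary motors (5.61 ± 0.30) and NME7, a kinase of ciliated cells (4.26 ± 0.32), by edgeR with BH adjusted p = 1.78e-05 and 0.000143. PTGDS, the prostaglandin D synthase of the leptomeninges, averaged 2221 CPM in cattle brain, 5186 in sheep brain and 0.0258 in goat brain. Its goat partner lies on the other strand than in cattle on chromosome 11, where EIF5B, GREB1, NPAS2 and SLC30A3 keep theirs, so a wrong partner is not ruled out. Goat brain had 0 counts of RPL29 (uncertain, near-identical copies), PPDPF and LRRC73, at least 5754-fold, 2006-fold and 1717-fold lower. ATP5MC1, also uncertain for the same reason, stood at 60.9, 1.19 and 325 CPM in cattle, sheep and goat brain. The goat model of PPDPF has 348 bases against 855 in cattle and 766 in sheep, and whether that model makes its 0 counts was not tested.

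Between species in brain, 2205 genes of 11919 differed for cattle against sheep (718 higher in cattle), 2195 for cattle against goat (986) and 1454 for sheep against goat (1018 higher in sheep), by edgeR at a BH adjusted p below 0.05 and a 2-fold difference. Against the mean of the other 2, cattle differed in 2174 genes (874 higher), sheep in 1762 (1360 higher) and goat in 1645 (754 higher). These counts moved with single libraries. Cattle against sheep gave 890, 1018 and 1055 without cattle brain A, B or C. Cattle against goat gave 1071, 1161 and 1374 without these, 1319 without goat brain A and 3342 without sheep brain C, as it did without sheep brain C and goat muscle C. Sheep against goat gave 590, 737 and 820 without goat brain A, B or C. The count for cattle alone was 1032, 1080 and 1233 without cattle brain A, B or C, that for sheep 1109 without cattle brain A, and that for goat 845 and 989 without goat brain A or B.

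In cattle brain some sterol genes were higher and some myelin and ribosomal genes lower than in the others. The isomerase IDI1 was higher in cattle brain by 2.16 ± 0.23, SQLE by 1.74 ± 0.20 and the reductase DHCR7 by 2.05 ± 0.30 (edgeR, BH adjusted p = 0.000393, 0.000656 and 0.00178). MOG, a myelin protein with 22.8, 118 and 142 CPM in cattle, sheep and goat brain, was lower by -2.51 ± 0.40 and OPALIN by -2.53 ± 0.48, and RPS2 by -1.92 ± 0.33 (edgeR, BH adjusted p = 0.00280, 0.00615 and 0.00418). The call of CLDN11 ended in most of the runs with a library left out. IDI1, OPALIN, RPS2 and RPL5 lost theirs with no length correction. The lists gave 0.97 for sterol synthesis (6 of 14 higher, 7 over the list alone), -1.28 for myelin (5 of 13 lower, 6 over the list alone) and -1.19 for ribosomal proteins (8 of 14 lower, 10 over the list alone), with camera, BH adjusted p = 0.000422, 0.0327 and 0.000156, and 0.935 for each with an estimated correlation. The myelin list lost its call without goat brain A, cattle brain C or sheep brain A or B. Sheep brain was lower in sterol synthesis (-0.77, 3 of 14, 5 over the list alone) and higher in ribosomal proteins (0.79, 2 of 14), with camera, BH adjusted p = 0.00875 and 0.0322, and 0.901 for both with an estimated correlation. The ribosomal call ended without sheep brain C, sheep brain B, cattle brain C or goat brain B, and without sheep brain C the ribosomal median was 0.38 and the sterol median -0.57. In goat brain the T-cell receptor chains CD3E and CD3D were higher by 4.45 ± 0.45 and 4.03 ± 0.43 (edgeR, BH adjusted p = 0.000493 and 0.000536), with CD3E at 9.04 CPM (SD 1.47) against 0.0720 in cattle and 2.41 in sheep. The lymphocyte list (2.21, 5 of 8) and the nuclear respiratory list (0.54, 4 of 15) passed with camera, BH adjusted p = 0.00874 and 0.0104, and gave 0.324 and 0.939 with an estimated correlation. COX5A and NDUFB5, higher by 1.45 ± 0.26 and 1.13 ± 0.23, lost their calls with no length correction, as did the respiratory list, which also lost its call without sheep brain A.

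The pairs of species repeated these lists in brain. Against sheep, cattle brain was lower in ribosomal proteins (-1.22, 9 of 14, 10 over the list alone) and higher in sterol synthesis (1.31, 6 of 14, 8 over the list alone), with camera, BH adjusted p = 0.000310 and 0.000289, and 0.919 for both with an estimated correlation. Without sheep brain C these medians were -0.83 and 0.98. Against goat, cattle brain was lower in myelin (-1.82, 5 of 13, 6 over the list alone), lymphocyte (-2.53, 5 of 8, 6 over the list alone), respiratory (-0.63, 5 of 15) and ribosomal genes (-1.11, 6 of 14, 8 over the list alone) and higher in sterol synthesis (0.87, 4 of 14, 6 over the list alone). Their camera, BH adjusted p were 0.00977, 0.00769, 0.00785, 0.00213 and 0.00769, and with an estimated correlation 0.444 for lymphocytes and 0.890 for the others. Without goat brain A the myelin median fell to -1.01 and its call was lost (camera, BH adjusted p = 0.121). Sheep and goat brain differed in no list.

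Cattle muscle exceeded both others in SLC16A6, a carrier of ketone bodies, with 418 CPM (SD 308) against 2.45 and 1.79 (7.63 ± 0.42), in the clock factor NPAS2 with 323 (SD 70.8) against 2.86 and 2.49 (6.91 ± 0.24), in SLC7A8 (6.24 ± 0.44) and in GREB1 (5.34 ± 0.40), by edgeR with BH adjusted p = 1.41e-06, 1.43e-07, 5.92e-06 and 7.94e-06. It fell below them in CFAP70, an axonemal protein, by -5.03 ± 0.47 (edgeR, BH adjusted p = 2.43e-05), and, with the doubt over copies noted for brain, in TPI1 by -6.94 ± 0.32 and RPL19 by -4.87 ± 0.32 (6.29e-07 and 4.66e-06). COX6A2, the muscle form of a cytochrome oxidase subunit, averaged 1509 CPM in goat muscle, 334 in sheep and 0.0165 in cattle. Its models have 294 bases in goat, 752 in sheep and 1046 in cattle. Whether the model, its counting or a wrong partner makes the low cattle value was not tested. Sheep muscle exceeded in EFCAB7, a ciliary protein, with 2434 CPM (SD 524) against 7.46 and 11.2 (8.06 ± 0.23), MIGA1 (5.92 ± 0.27) and NR4A2 (5.24 ± 0.35), and fell below in NME7 (-4.74 ± 0.40), MYH6 (-4.35 ± 0.68) and PITX3, a homeobox factor (-4.11 ± 0.38), by edgeR with BH adjusted p = 2.9e-08, 1.1e-06, 9.91e-06, 3.03e-05, 0.000891 and 5.02e-05. The sheep model of EFCAB7, on chromosome 1 from 40882828 to 41025031, has 32 exons against 15 in cattle and 14 in goat. It is therefore doubtful that the same gene was measured, and the doubt given above for MIGA1 holds here too. Goat muscle exceeded in CFAP70 (4.76 ± 0.36) and POLR2K of RNA polymerase (4.28 ± 0.21), and fell below in DDX3X, an RNA helicase (-6.10 ± 0.22), by edgeR with BH adjusted p = 8.85e-06, 1.48e-06 and 3.46e-07. The goat model of POLR2K has 177 bases against 1798 in cattle and 859 in sheep, so the length correction makes much of its value, and that of DDX3X has 7 exons against 20 in both others. TUBA4A stood at -11.64 ± 0.57 (edgeR, BH adjusted p = 1.48e-06) and RPL29 was at least 5596-fold lower in goat muscle, both uncertain for copies. PPDPF was at least 10470-fold lower there, with the doubt over its model noted for brain. ATP5MC1 averaged 95.7, 1.88 and 594 CPM.

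Between species in muscle, 3664 genes of 11141 differed for cattle against sheep (1664 higher in cattle), 4206 for cattle against goat (1894) and 2951 for sheep against goat (1361 higher in sheep), by edgeR at a BH adjusted p below 0.05 and a 2-fold difference. Cattle differed from the mean of the others in 3685 genes (1664 higher), sheep in 2585 (1344) and goat in 3134 (1795). These counts cannot be set against those in brain, since for cattle against sheep the same simulated 4-fold change was called in 46.3% of the changed genes in brain (median fitted log2 1.97) and in 87.5% in muscle (1.95). No single library moved the counts in muscle by more than 1.5 times. The median log2 for cattle against goat went from -0.04 to -0.11 with upper-quartile scaling.

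Some early-response genes were higher and some genes of slow fibres lower in sheep muscle. EGR3 was higher in sheep muscle by 5.65 ± 0.59, the nuclear receptor NR4A1 by 3.14 ± 0.38, FOSB by 4.70 ± 0.92 and the phosphatase DUSP1 by 2.25 ± 0.37 (edgeR, BH adjusted p = 9.83e-05, 0.000251, 0.00289 and 0.00121). NR4A1 averaged 1787 CPM in sheep muscle (SD 522) against 171 in cattle and 207 in goat. The slow troponins TNNC1 and TNNT1 were lower by -2.88 ± 0.46 and -1.66 ± 0.35, CSRP3, a stretch sensor of the Z-disc, by -3.44 ± 0.63 and the tropomyosin TPM3 by -2.38 ± 0.50 (edgeR, BH adjusted p = 0.000978, 0.00416, 0.00202 and 0.00414). CPT1B, the gate of fat entry into mitochondria, was lower by -1.36 ± 0.26 and FABP3 by -2.21 ± 0.45, and ESAM and KDR of endothelium were higher by 2.21 ± 0.31 and 1.46 ± 0.21, with SLC2A1 lower at -1.42 ± 0.38 (edgeR, BH adjusted p = 0.00266, 0.00359, 0.000497, 0.000538 and 0.0137). PENK, an opioid precursor, was higher by 4.46 ± 0.70 (edgeR, BH adjusted p = 0.000866), and TAC1 averaged 5.54 CPM against 0.0159 in cattle and 0.682 in goat. The lists gave 2.995 for early-response genes (5 of 6, 6 over the list alone), -1.59 for slow fibre (7 of 11), -0.69 for fat oxidation (4 of 11), 0.69 for endothelium (3 higher and 1 lower of 10) and 2.97 for striatum (4 of 4), with camera, BH adjusted p = 0.0199, 0.0243, 0.0337, 0.0337 and 0.0337, and 0.620 for each with an estimated correlation. Fat oxidation and endothelium lost their calls without cattle muscle A, sheep muscle B or goat muscle B, striatum without cattle muscle A or goat muscle C, and slow fibre among first-pass matches. The mean log2 of the slow-fibre list was 8.99, 9.77 and 9.76 in sheep muscle A, B and C. Goat muscle C lay within these at 9.49, against 11.25 and 11.09 in goat muscle A and B. Cattle muscle ran from 10.65 to 12.04. The labels do not name the muscle, and whether it differed between libraries was not tested. UCP3 and SLC2A1 lost theirs without sheep muscle A or C, and PPP1R1B and RGS9 without sheep muscle B.

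Some lymphocyte genes were lower in cattle muscle and some higher in goat muscle. CD3E was lower in cattle muscle by -3.26 ± 0.35 and the B-cell chain CD79A by -3.59 ± 0.60, and in goat muscle CD3E was higher by 2.60 ± 0.29 (edgeR, BH adjusted p = 5.29e-05, 0.000713 and 7.46e-05). The endothelial receptors KDR and TIE1 were lower in cattle muscle by -1.66 ± 0.24 and -1.23 ± 0.19, and goat muscle was higher in RPL10A by 1.89 ± 0.26 and NDUFB5 of complex I by 1.68 ± 0.17 (edgeR, BH adjusted p = 0.000279, 0.000459, 0.000294 and 4.6e-05). In cattle the lymphocyte list gave -2.17 (7 of 8 lower) and endothelium -1.23 (7 of 10), with camera, BH adjusted p = 0.0346 for both, and 0.897 for both with an estimated correlation. In goat the lymphocyte list gave 1.78 (6 of 8), the nuclear respiratory list 0.90 (6 of 15) and ribosomal proteins 0.87 (6 of 14), with camera, BH adjusted p = 0.0384, 0.0140 and 0.00288, and 0.757 for each with an estimated correlation. Both lymphocyte calls ended without goat muscle C, and RPL18 of goat lost its call without that library too. CDH5, COX5A, RPL5 and RPL8 lost theirs with no length correction, and so did the respiratory and ribosomal lists of goat.

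Between pairs of species in muscle, cattle was lower than sheep in endothelial genes (-1.28, 7 of 10, with 1 higher, camera, BH adjusted p = 0.0306, and 0.734 with an estimated correlation). Cattle was lower than goat in lymphocyte (-2.83, 7 of 8), respiratory (-1.30, 8 of 15) and ribosomal genes (-0.82, 6 of 14), with camera, BH adjusted p = 0.0193, 0.0141 and 0.0141, and 0.888 for each with an estimated correlation. Sheep was lower than goat in ribosomal proteins (-0.96, 7 of 14) and higher in early-response genes (3.15, 5 of 6), with camera, BH adjusted p = 0.00523 and 0.0113, and 0.702 for both with an estimated correlation. The ribosomal median was -0.73 without goat muscle C and the early-response median 4.25 without goat muscle B.

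**Figure D3:**
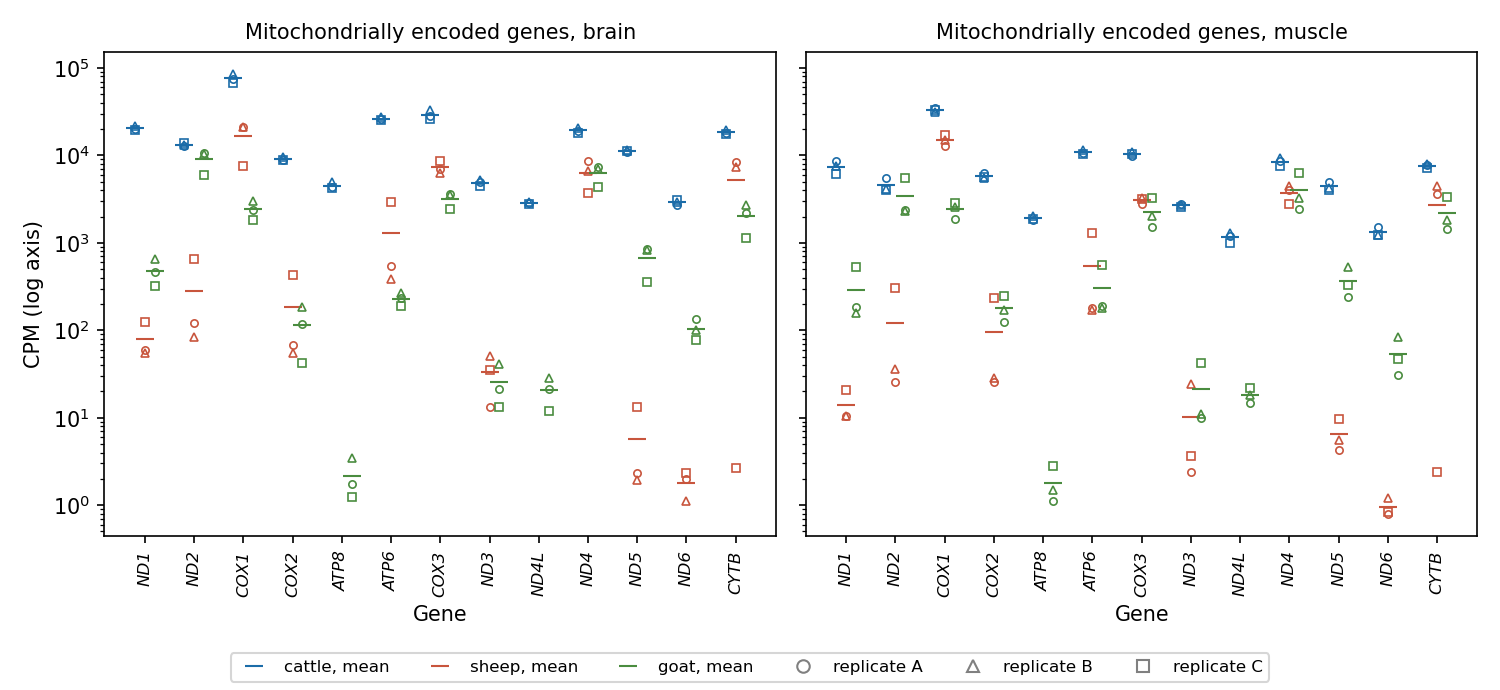
Levels of the protein-coding mitochondrial genes in each library, 13 in cattle and goat and 11 in sheep, which lacked ATP8 and ND4L, on a log axis, for brain and for muscle. Symbols mark the replicate letter and bars the mean of each species.

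Mitochondrially encoded genes took a far larger part of the counts in cattle than in sheep or goat. They made up 24.5% of counts in cattle brain (SD 1.90) and 10.1% in cattle muscle (SD 0.474), against 4.03% and 2.71% in sheep and 3.34% and 2.20% in goat. Single genes differed widely: relative to cattle brain the log2 ratios in sheep brain ran from -10.92 to -1.62 with a median of -5.55, and in goat brain from -11.01 to -0.56 with a median of -4.98. CYTB, a subunit of complex III, stood at 8471 and 7418 CPM in sheep brain A and B but 2.66 in C, and at 3599 and 4522 in sheep muscle A and B but 2.37 in C. COX1, of cytochrome oxidase, stood at 21370, 21310 and 7562 CPM in sheep brain A, B and C and at 12850, 15050 and 16950 in sheep muscle A, B and C. These levels are CPM on the library total, without the trimmed-mean scaling or length correction of the other genes. No gene of this list was matched by exons, so none entered the fits between species.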

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

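All tests of chance in this part were chosen after the counts were seen, and of the tests on gene models only those for the length of the models between cattle and sheep muscle and for the shift shared by both tissues between cattle and goat muscle were written before their result.

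EGR3, KY and MYH6 between cattle and sheep, ACSBG1 and MSRA between cattle and goat, and NR4A2 and CHRNE between sheep and goat were among the genes whose difference between brain and muscle was not alike in the species. They stood among 3029 genes over all species, 2396 for cattle against sheep, 1607 for cattle against goat and 868 for sheep against goat. Of 100 splits of the libraries only the real one, 1 in 100, gave a count as large as 3029, 2396 or 1607. The highest other count was 531 over all species and 1088 for a pair. These splits dealt the species labels within each tissue, so they mix species in a group and widen its spread. They cannot exclude chance for the interaction itself. For the 868 of sheep against goat, 3 of 100 splits gave as many and the highest was 1088.

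Sterol genes such as FDFT1 shifted towards brain in cattle, with list medians of 1.996 against sheep and 0.88 against goat. For sheep against goat the sterol median was -1.04, or -0.76 without sheep brain C. Ribosomal proteins such as RPL5 gave -1.11 for cattle against sheep and 1.18 for sheep against goat, but -0.71 and 0.68 without sheep brain C. FOXO1, GADD45A and FBXO32 of the atrophy list gave -2.54 for cattle against goat, and the early-response genes with EGR3 gave -2.78 for sheep against goat, or -4.18 without goat muscle B. None of these 7 calls was kept by camera with an estimated correlation, so they rest on the correlation that was set.

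Genes such as EIF5B in sheep brain and DDX3X in goat muscle differed between species where their gene models differ too, and the lengths of the models may explain part of the calls. The share of genes called among models within 1.2 times of each other, over the share among models at least 2 times apart, was 0.188 for sheep against goat in brain, which fits that cause, and 0.790 and 0.733 for cattle against sheep and cattle against goat in muscle, which argue against it as the main cause only, since log2 and length ratio still correlated at -0.180 and -0.273 there. It was 0.543 and 0.339 for cattle against sheep and cattle against goat in brain and 0.486 for sheep against goat in muscle, which decide nothing. Log2 and length ratio correlated at -0.146, -0.420 and -0.374 in these, in the same order, and at -0.340 for sheep against goat in brain. The negative sign means that the species with the longer model tended to read lower after the length correction. Of genes called in muscle, 80.6% had the same sign in brain for cattle against goat, just over the 80% set for a shift of the gene shared by both tissues, and 70.3% and 73.6% for cattle against sheep and sheep against goat, between the limits, where all genes tested in both tissues gave 69.4%, 61.4% and 60.5%. Whether such a shift comes from gene models, from copies sharing reads or from the species stays open.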

How the results depend on the processing

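Among the named values and lists called in the main fit, none reversed its direction under a setting that covered it. A change of sign in results not called was not looked for, and neither was the direction with an estimated correlation. With a log2 fold of at least 2, genes higher in muscle numbered 1871 in cattle, 1753 in sheep, 1844 in goat, 1202 over all species and 612 in each of the 3 species, since fewer genes pass a larger fold. The interaction then held 1970 genes, 1395 for cattle against sheep and 1016 for cattle against goat. In brain, cattle against sheep gave 1056, cattle against goat 966, sheep against goat 679, and cattle, sheep and goat against the others 852, 668 and 575. In muscle these were 1423, 1701, 935, 1291, 787 and 948. With no fold threshold muscle gave 4446 for sheep against goat and 5903, 4605 and 5259 for cattle, sheep and goat against the others. DESeq2 gave 1668 for the interaction of sheep against goat, and the cause was not tested.

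Only genes with exonic lengths within 1.2 times left 632 higher in brain and 426 in muscle over all species, 381 in the interaction, and 340, 224 and 68 for its pairs cattle against sheep, cattle against goat and sheep against goat. In brain these pairs gave 235, 165 and 74 and the species against the others 221, 166 and 113. In muscle the pairs gave 533, 584 and 320 and the species 547, 367 and 401, and 5 lists were called over all species. The stricter match gave 1430 and 1093 over all species, 775 and 529 in each of the 3 species, 1138 in the interaction and 970, 652 and 244 for its pairs. It gave 723, 666 and 490 for the pairs and 625, 593 and 483 for the species in brain, 1409, 1574 and 1052, then 1385, 914 and 1074 in muscle, and 10 lists. Both settings hold far fewer genes. First-pass matches alone gave 1402 for cattle against goat and 1071 for goat in brain, and no length correction gave 1068 for goat in brain.

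Leaving out sheep brain C and goat muscle C gave 2756 for the interaction of cattle against goat and 3342 for cattle against goat in brain, and the cause was not tested. Leave-one-out moved the interaction of cattle against goat to 1067 without cattle brain replicate A and 2682 without sheep brain replicate C. It moved that of sheep against goat to 437 and 491 without goat brain replicate A and C, to 448, 420 and 437 without sheep muscle replicate A, B and C, and to 545 without goat muscle replicate C, with a highest count of 1217 without sheep brain replicate A. In brain, cattle against sheep went to 890, 1018 and 1055 without cattle brain replicate A, B and C. Cattle against goat went to 1071, 1161 and 1374 without these, to 3342 without sheep brain replicate C and to 1319 without goat brain replicate A. Sheep against goat went to 590, 737 and 820 without goat brain replicate A, B and C. Without sheep brain replicate C the highest counts in brain were 2449 for cattle against sheep, 1923 for sheep against goat, 2665 for cattle and 2273 for goat against the others, and that of sheep was 2021 without sheep brain replicate A. Cattle against the others went to 1032, 1080 and 1233 without cattle brain replicate A, B and C, sheep to 1109 without cattle brain replicate A, and goat to 845 and 989 without goat brain replicate A and B. In these fits groups of 2 share the spread of the others.

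With the replicate letter as a block the interaction held 1840 genes, 977 for cattle against goat and 273 for sheep against goat. Under the block 12 of 403 named values lost their call and 1 gained one, and of 670 list tests 2 lost theirs and 13 gained one. The labels do not tie the letters to animals. The residuals of brain and muscle of letters A, B and C correlated at 0.0400, 0.0445 and 0.0353 in sheep, -0.0200, 0.00663 and -0.0477 in cattle and 0.149, -0.195 and -0.0378 in goat. In sheep each brain sample correlated best with the muscle sample of its own letter, a hint of pairing from the data and not from the design, and in cattle and goat this did not hold, so no pairing by letter was taken. Lists called over all species numbered 9 with an estimated correlation and 35 with fry. The correlation of the same tissue between species was 0.7999 on the most variable genes alone. Of 403 named values limma-voom weakened 12 and strengthened 1, and of 331 values no length correction weakened 15 and strengthened 2. Leaving out cattle brain replicate A weakened 14 of 293. Over all list tests 119 of 670 were weaker with an estimated correlation, and with fry 11 were weaker and 131 stronger. A prior count of 0.5 left the rank correlations as they were, since it cannot change ranks. Not run was the removal of mitochondrially encoded genes. None was matched, so the fits between species held none of them. The fits within a species did hold them, at 24.5% of counts in cattle brain and 10.1% in cattle muscle, and were not repeated without them.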

Other observations

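The tests on the depth of sheep brain C were written before their result, and those on muscle RNA and gene length in it, on mitochondrial genes and on chance were chosen after the values were seen.

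Markers of cortex stood high in brain of all 3 species, though the labels name no region. SLC17A7, which loads glutamate into vesicles, averaged 1131, 726 and 719 CPM in brain of cattle, sheep and goat, and CUX2, a transcription factor of upper cortical layers, was higher in brain by 7.42 ± 0.45 (edgeR, BH adjusted p = 2.63e-11). ZIC2 and CA8 of the cerebellar list were higher by 7.27 ± 0.35 and 6.09 ± 0.41, and PENK and RGS9 of the striatal list by 6.25 ± 0.69 and 3.76 ± 0.31. Hormone genes were low: AVP averaged 1.28, 6.44 and 5.22 CPM, and HCRT of orexin neurons 0.00795, 1.22 and 0.0345. All 8 cortical genes were higher in brain (median 8.22, 8.12 with the floor), with 6 of 8 cerebellar (3.22) and 4 of 4 striatal genes (4.20), by camera with BH adjusted p = 3.04e-05, 0.0136 and 0.0221, and 0.0182, 0.144 and 0.145 with an estimated correlation. Choroid plexus and ependyma (3 of 4 higher and 1 lower, 5.34, 5.42 with the floor), hindbrain (3 higher and 2 lower of 5, 2.31, 1.64 with the floor) and hypothalamus (4 higher and 1 lower of 7, 3.74, 1.06 with the floor) were not called (camera, BH adjusted p = 0.415, 0.931 and 0.350).

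Single stress and clock genes moved to either side between the tissues. ATF3, a stress transcription factor, was higher in muscle at -5.59 ± 0.55 and FOS at -2.95 ± 0.48, with EGR3 higher in brain by 2.94 ± 1.13 (edgeR, BH adjusted p = 3.16e-08, 2.46e-05 and 0.0265). BAG3, a co-chaperone of muscle, stood at -4.28 ± 0.19 and HSPH1 at 2.04 ± 0.22, the clock repressor PER2 at -1.26 ± 0.16 and DBP, an output of the clock, at 2.01 ± 0.32. The antiviral RSAD2 stood at -2.38 ± 0.35 and IFI6 at 2.39 ± 0.49, and CD2 of T cells at -3.36 ± 0.35. Against the other genes no call was made for the early-response (1 higher and 4 lower of 6, -2.74), heat shock (1 and 2 of 7, -0.22), interferon (2 and 5 of 9, -1.13), circadian (1 and 4 of 10, -0.68) and lymphocyte lists (1 and 4 of 8, -1.79), with camera, BH adjusted p = 0.0585, 0.559, 0.476, 0.142 and 0.226, while fry, which tests a list against no change, called all 5 (BH adjusted p = 5.41e-05, 3.17e-05, 0.0381, 3.34e-10 and 3.40e-05). The red blood cell list, 3 genes, had means from -5.77 in goat muscle C to -2.44 in cattle brain C.

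Sheep brain C was low in ion channel genes, at a mean log2 of 4.42 against 6.31 and 6.26 in A and B, and in excitatory neuron genes, at 5.78 against 7.36 and 7.46, and higher in ribosomal proteins, at 9.63 against 8.38 and 8.94. The fall was not only neuronal: astrocyte genes stood at 7.28 against 9.11 and 9.46, myelin at 5.89 against 7.16 and 7.13 and oligodendrocyte precursors at 4.19 against 5.81 and 5.84. The microglial list, at 4.63 against 4.56 and 5.06, was not below both. Lower depth was not at issue, since C held the most counts of its group (30432512), and the correlation of 0.815 with A and B after thinning adds nothing to that. Muscle RNA is argued against by sarcomere genes at 0.304% of their muscle level. A bias with gene length is not the whole cause, since the correlation rose only to 0.831 with the trend removed. Another brain region or damaged RNA could give such a library and stays open.

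Sheep and goat had low mitochondrial shares that differed gene by gene, with CYTB at 2.66 CPM in sheep brain C and 8471 in A. The SD of the log2 ratio of sheep to cattle brain over these genes was 3.44, which fits reads of single genes going uncounted and argues against an even fall. Sheep brain C stood above A and B in ND1, ND2, COX2, ATP6, COX3, ND5 and ND6 and below them in COX1, ND4 and CYTB. ATP6 stood at 539, 383 and 2934 CPM in sheep brain A, B and C and at 178, 171 and 1281 in sheep muscle. Departures of sheep A and B from the other letters correlated at 0.894 and 0.872 between brain and muscle over 11 genes (Pearson). Those of C from A and B correlated at 0.964, or 0.8545 by Spearman. CYTB weighed most in C, with log2 departures of -11.52 in brain and -10.71 in muscle. The departures of the 3 letters are not independent, since each is taken from the others. The likeness in C could arise if both its libraries came from an animal whose mitochondrial sequence matched the reference otherwise than those of A and B. A poor match alone would not give the higher values. In goat the departures of A, B and C correlated at only 0.154, -0.392 and 0.0498. That explanation was prompted by the values of sheep, and the residuals of nuclear genes of the same letter correlated at no more than 0.0445 between the tissues in sheep, so it stays open.

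What counts arise by chance was asked with other splits of the labels. Such splits put both tissues or several species into a group and widen its spread, so their low counts cannot exclude chance by themselves. CKM, CHGB and the other genes called in each of the 3 species met 1 of 100 splits with as many, the real one, and 0 was the highest other count. For genes higher in brain or muscle over all species the real split alone reached its count (1 of 100), with 2769 the highest other. In brain the real split alone did so for each pair (1 of 100, highest other 1163) and for each species against the others (1 of 100, highest other 1404), and in muscle for each pair (1 of 100, highest other 2661) and for cattle and goat against the others (1 of 100, highest other 2878). For sheep muscle against the others 3 of 100 splits gave as many. Within a species only 10 splits exist, too few to exclude chance, and 1 of 10, the real one, gave as many, with 0 the highest other.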
